A study of Mus musculus with 6 samples.

How the data were processed

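RNA was measured in 6 libraries of lineage-depleted bone marrow from Dek -/- C57BL/6 mice, 3 treated with vehicle and 3 with DEK. Per the labels' protocols, marrow was flushed from the femur, lineage-marked cells were removed on columns, RNA was isolated and treated with DNase, and libraries were made with a kit that selects polyadenylated RNA and keeps strand. The series' design text also speaks of lineage-positive cells, which are not among these libraries and were not analysed here.

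The deposited table holds read counts per gene for 24421 genes. Per the file headers, the counts were made with featureCounts 1.6.1 over exons grouped by gene on the mm10 build, from 1 alignment per library, all from lane 6, with no strand option and no option for paired reads. Per the submitters' processing notes, the tools were Trim Galore, STAR, HTSeq and edgeR. The notes name HTSeq where the header names featureCounts, and the header describes the counts used. No option for overlapping genes was set, so a read that lies in exons of more than 1 gene was not counted. Because the counting did not use strand, this also applied to genes on opposite strands, and reads of an unannotated transcript opposite a gene would be counted for that gene. For this reason, named genes whose exons overlap another gene are given as uncertain. The table has no mitochondrially encoded genes, so 0 of the 13 on that fixed list could be examined. Of all fixed symbols, 19 had no row, 6 of them outside the mitochondrial list. Coordinates are the outer exon bounds the table gives on mm10.

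All later steps were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Of 18049 genes with a read in any library, 13803 passed filterByExpr and were tested. Library sizes were scaled by TMM. The main comparison was edgeR's quasi-likelihood test with robust dispersion and no block, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are DEK minus vehicle, and their standard errors come from the F statistic. Log2 CPM values use a prior count of 2. CPM values are given as mean and SD over 3 libraries. Depth ran from 34875736 to 49128378 counts per library. Reads carry no molecular identifiers, so intervals of shares cover counting error only.

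The replicate number as a block was an alternative set down in advance. The labels do not say that equal numbers share an animal or a day. The check of pairing was the correlation across genes of each library's deviations from its group mean, which was 0.55, 0.56 and 0.80 for equal numbers 1, 2 and 3, and each library correlated best with its own number. By the rule that every pair must exceed a correlation of 0.1, the numbers were taken as pairs. Values within pairs are therefore given as well, and most values of single genes and lists below come from that fit. In the Results, fold changes and their adjusted p are within pairs unless marked as unpaired. Unpaired values are printed only for the counts of called genes and lists, the genes with the smallest unpaired p, the NF-kB list, a few standard errors and the alternatives. Unequal numbers exceeded 0.1 too, at 0.52 for vehicle 2 with DEK 1 and 0.41 for vehicle 1 with DEK 2. The rule thus cannot show that numbers 1 and 2 pair the samples. Most of this agreement came from the libraries numbered 3: between numbers 1 and 2 alone, the difference correlated by only 0.12 across the groups. The common biological coefficient of variation was 33.1% without the block and 13.1% with it. Genes are not independent replicates. The p-values of single genes measure the spread between these libraries, and the labels do not say whether libraries stem from different animals. Fisher's exact test takes genes as independent, and camera with the preset correlation compares list genes with other genes. The p-values of these 2 list tests therefore do not measure replication between libraries.

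Before the data were examined, the design, the alternatives, 32 gene lists and the rule for naming genes were fixed. The rule took Dek, then, among called genes with a mean of at least 1 CPM, an established symbol and non-overlapping groups, the 12 largest rises and 12 largest falls, or the 10 smallest p where fewer than 10 genes passed. It also took up to 4 called members per list, or 2 uncalled ones. Because the unpaired test called 0 genes, its 10 smallest p are named. The same rule was applied to the fit within pairs with the same direction in all 3 pairs in place of non-overlapping groups, a change made after the data were seen. Of the 13803 genes tested, 993 (7.19%) had groups that did not overlap. Chance alone gives 10% if the 6 libraries are unrelated and alike in spread. The libraries numbered 3 stood apart in both groups, so 10% is not the chance share here and the 2 values cannot be compared.

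Of the lists, 31 had at least 5 members tested. They were tested with camera on log2 CPM with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Fry tests whether the genes of 1 list move, on balance, one way, and neither it nor its mixed form compares a list with other genes. Frequencies of called genes in a list used a one-sided Fisher's exact test against all other genes tested, adjusted over the lists and both directions. Bootstrap intervals of list medians used 2000 draws over genes at 95%. Measures of single libraries were compared with exact two-sided permutation tests, whose smallest possible p is 0.1. Shares have Wilson intervals.

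The fits were tested on simulated data drawn from the means and depths of these libraries, with 200 genes changed. Means were set by replicate number and the spread came from the fit with the block, so each simulated pair shared a replicate effect. Each gene was drawn independently of the others. Without the block, edgeR recovered 0% of genes changed 1.5-fold, 2.99% changed 2-fold and 65.2% changed 4-fold, and it called 0 unchanged genes of 13622 in the run. With the block it recovered 46.3%, 68.7% and 97%, and 14 of its 155 calls (9.03%) were unchanged genes, above the nominal 5%. The gain with the block was built into the simulation and cannot show that the real numbers are pairs. With the NF-kB list raised 1.5-fold among 13651 genes, camera with the preset correlation called it in both fits and called 0 other lists. Because genes were drawn independently, this cannot show that the preset avoids false list calls where genes are correlated. The estimated correlation called it without the block (adjusted p = 0.0123) but not with it (adjusted p = 0.182).

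Alternatives covered the scaling, the tool, the filter on low counts, the block, leaving out each library or pair, thinning to the smallest library, the thresholds and the list tests. Alternatives to the fit within pairs, and those that treat the libraries numbered 3 as a batch or leave them out, were chosen after seeing the data. A pseudocount alternative was planned only for normalized values and was not run, since the table holds counts.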

Results

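Bone marrow cells of C57BL/6 mice labelled as knockouts of the Dek gene (Dek -/-) were profiled by sequencing of polyadenylated RNA. Dek encodes a chromatin-binding nuclear protein that some blood cells can also release. The marrow had been flushed from the femur and depleted of lineage-marked cells on magnetic columns, a step that removes most mature blood cells and enriches progenitors. The title of the series gives the question, which was how the transcripts of these cells differ after treatment with DEK protein supplied from outside. There were 3 libraries from vehicle-treated cells and 3 from DEK-treated cells, numbered 1 to 3 in each group. The dose, the length of treatment and the source of the protein are not given in the labels. Reads counted in genes came to 48867857, 38060873 and 34875736 in vehicle replicates 1, 2 and 3, and to 42496076, 49128378 and 48067741 in DEK replicates 1, 2 and 3.

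Dek itself (chromosome 13, 47084767 to 47106221, minus strand, mm10) had counts of 863, 672 and 733 in the vehicle libraries and 781, 869 and 712 in the DEK libraries. Its level was 18.7 ± 2.71 CPM (read counts scaled to a common library total; SD, n = 3) in the vehicle group and 17.0 ± 0.490 CPM (SD, n = 3) in the DEK group. The log2 fold change was -0.13 ± 0.13 (SE) within pairs of equal replicate number (adjusted p = 0.757, edgeR). The labels do not say which exons the knockout removes, and a count summed over the whole gene cannot show the loss of a part, so these values do not check the genotype. Exons of Kdm1b lie on the opposite strand within the same interval, and because the counting took no account of strand and left out reads in exons of more than 1 gene, reads of the shared stretch are missing from the Dek count.

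Both libraries numbered 3 stood apart from the other 4 in their content of neutrophil transcripts. The fixed neutrophil markers took 7.62% of counts in vehicle replicate 3 and 6.58% in DEK replicate 3, against 1.64 to 1.71% in the other vehicle libraries and 1.75 to 1.94% in the other DEK libraries. Wilson 95% intervals of these shares reached at most 0.0088 percentage points to either side and cover counting error only. S100a9, which encodes a calcium-binding protein abundant in neutrophils, stood at 26300 and 24380 CPM in the libraries numbered 3 and between 1911 and 2555 CPM in the rest. The first principal component of the 500 most variable genes carried 77.7% of their variance and set both libraries numbered 3 apart. The second carried 9.73% and separated the vehicle from the DEK libraries. The share of neutrophil transcripts itself averaged 3.66 ± 3.43% (SD, n = 3) with vehicle and 3.42 ± 2.73% (SD, n = 3) with DEK (exact two-sided permutation p = 1, where 0.1 is the smallest p that 3 libraries against 3 can give). The precursor of ribosomal RNA, Rn45s, took 4.89% of counts in vehicle replicate 1 (Wilson 95% interval 4.88 to 4.89%) and 0.159 to 0.331% in the other libraries.

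**Figure D1:**
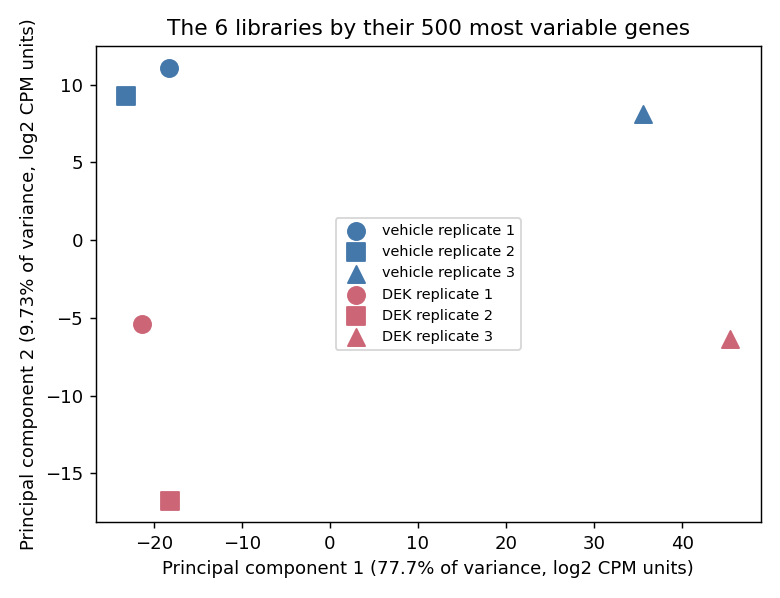
Position of each library on the first principal component (horizontal, 77.7% of variance) and the second (vertical, 9.73%) of the 500 most variable genes, in log2 CPM units. Color gives the treatment and marker shape the replicate number. Both triangles, the libraries numbered 3, lie at the right, and the 3 vehicle libraries lie above the 3 DEK libraries.

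Genes of the NF-kB response, which codes for inflammatory mediators and for the feedback inhibitors of the pathway, were higher after DEK treatment within the 3 pairs of equal replicate number, where 16 of 31 rose and 0 fell (camera adjusted p = 1.13e-17; adjusted p = 0.79 with an estimated correlation). Il1b, the gene of the cytokine interleukin 1 beta, rose 3.92-fold (log2 fold change 1.97 ± 0.16, SE), and Clec4e, which encodes a receptor for microbial glycolipids, rose 2.57-fold (1.36 ± 0.12). Class II antigen presentation genes H2-Eb1 and H2-Ab1 rose 1.58-fold and 1.56-fold (0.66 ± 0.11 and 0.64 ± 0.11). In the other direction, Scgb1a1, a secretoglobin best known from airway epithelium, fell 32.7-fold (-5.03 ± 0.34), the growth factor gene Igf1 fell 3.78-fold (-1.92 ± 0.24) and the complement gene C1qb, a marker of macrophages, fell 2.99-fold (-1.58 ± 0.22). Eosinophil markers were lower as a group (camera adjusted p = 3.44e-07; adjusted p = 0.79 with an estimated correlation).

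None of these genes passed in the main fit, which takes no account of the replicate numbers. Without pairing, the log2 fold change was 1.98 ± 1.02 (SE) for Il1b, -1.39 ± 0.72 for C1qb and -4.99 ± 0.52 for Scgb1a1. The standard errors within pairs were smaller, at 0.16, 0.22 and 0.34. In the main fit, 0 of 13803 genes had an adjusted p under 0.05 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 360, fewer than the 5% of tested genes that such a cut gives without any effect. DESeq2 called 51 (32 higher and 19 lower) and limma-voom called 0. Within pairs, edgeR called 177 genes, 120 higher and 57 lower in the DEK libraries, and each of the 177 moved the same way in 3 of 3 pairs. Leaving out pair 1, 2 or 3 gave 181, 0 and 641 genes. Of these, 144 were higher and 37 lower without pair 1, and 327 higher and 314 lower without pair 3. With a fold change of at least 2 in all 3 pairs' fit, 24 were higher and 23 lower. The excess of higher genes thus varied with the pairs used and the cut. Without pair 2, none of the 47 called genes that the naming rule took kept its call. Their folds were 0.57 to 1.15 times those from all 3 pairs (median 0.93). These genes were chosen from all 3 pairs, and pairs 1 and 3 were in both fits, so folds of like size were likely in advance.

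The 10 genes with the smallest p in the unpaired fit, none of them past its threshold (adjusted p = 0.294 to 0.476, edgeR), were Scgb1a1, Pmp22, Marcksl1, Clec4e, Hpgds, Cd40, Mcoln3, Bcar3, Cp and Nfkbia. Each of them passed within pairs. Scgb1a1 (chromosome 19, 9083642 to 9087956, minus strand) had 265, 278 and 202 counts in the vehicle libraries and 4, 7 and 15 in the DEK libraries. Its level was 6.11 ± 0.794 CPM with vehicle and 0.192 ± 0.137 CPM with DEK (SD, n = 3 each), lower in 3 of 3 pairs (adjusted p = 0.000124, edgeR within pairs), and without pair 3 its fall was 53-fold. Pmp22 (chromosome 11, 63128982 to 63159547, plus strand), which encodes a peripheral myelin protein, went from 8.97 ± 1.64 to 1.71 ± 0.325 CPM (SD, n = 3 each; adjusted p = 0.000124, edgeR within pairs). Hpgds, the prostaglandin D synthase of blood cells, fell 3.67-fold, Mcoln3, an ion channel of endosomes and lysosomes, fell 6.31-fold, and the adaptor gene Bcar3 fell 2.41-fold. Marcksl1, which encodes an actin-binding protein, rose 2.39-fold (adjusted p = 0.00169, edgeR within pairs).

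The largest rises within pairs that the naming rule took were led by Smpdl3b (chromosome 4, 132732966 to 132757171, minus strand), the gene of a membrane-anchored phosphodiesterase. It went from 5.04 ± 1.76 CPM with vehicle to 42.4 ± 21.3 CPM with DEK (SD, n = 3 each), 7.94-fold (adjusted p = 0.0273, edgeR). Il1b (chromosome 2, 129364580 to 129371120, minus strand) had log2 differences of 1.54, 2.39 and 1.99 in pairs 1, 2 and 3 (adjusted p = 0.00293, edgeR), and its counts were highest in the libraries numbered 3, at 5938 with vehicle and 30231 with DEK. The other rises were Tnfaip8l3 5.37-fold, Slc4a11 3.67-fold, C1s1 3.51-fold, Ptgs2 3.26-fold, Cp 3.13-fold, Cd300e 2.81-fold, Zmynd15 2.45-fold and Mcam 2.37-fold, with adjusted p from 0.0152 to 0.0494 by edgeR. Without pair 3, the rise of Tnfaip8l3 was 10.1-fold, and Slc4a11, Cd300e and Mcam lost their calls. In DEK replicates 1, 2 and 3, Slc4a11 stood at 1.21, 1.58 and 8.26 CPM and Mcam at 1.88, 1.26 and 16.3 CPM. Ptgs2 encodes the inducible cyclooxygenase and Cp the ferroxidase ceruloplasmin. Tnfaip8l3, Slc4a11, C1s1 and Cd300e had means under 1 CPM in the vehicle group. With no filter on low counts, Smpdl3b and Cp were no longer past the threshold. Exons of Zmynd15 overlap those of Cxcl16 on the opposite strand, and exons of Cp overlap those of Hps3, so these values are uncertain, as is that of C1s1, which has a close paralog.

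The largest falls after Scgb1a1 included those of Gas6, a secreted ligand, and Mertk, a receptor it binds, which fell 4.56-fold and 4.28-fold (adjusted p = 0.0171 and 0.0133, edgeR). Axl, another receptor of Gas6 that was chosen after its value was seen, did not pass (adjusted p = 0.631, edgeR) and had log2 differences of -2.03, -1.64 and 0.05 in pairs 1, 2 and 3. Igf1 (chromosome 10, 87859056 to 87937047, plus strand) went from 11.4 ± 1.48 CPM with vehicle to 3.15 ± 1.503 CPM with DEK (SD, n = 3 each; adjusted p = 0.00927, edgeR). Fam198b fell 4.33-fold, Pianp 4.29-fold, the folate enzyme gene Aldh1l2 3.57-fold and the fatty acid binding protein gene Fabp3 3.25-fold. Klk1b11 fell 18.9-fold, from 96, 151 and 62 counts to 3, 2 and 13, or 10.8-fold without pair 2 and 51.3-fold without pair 3, and is uncertain because the kallikrein genes are a family of near-identical copies.

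**Figure D2:**
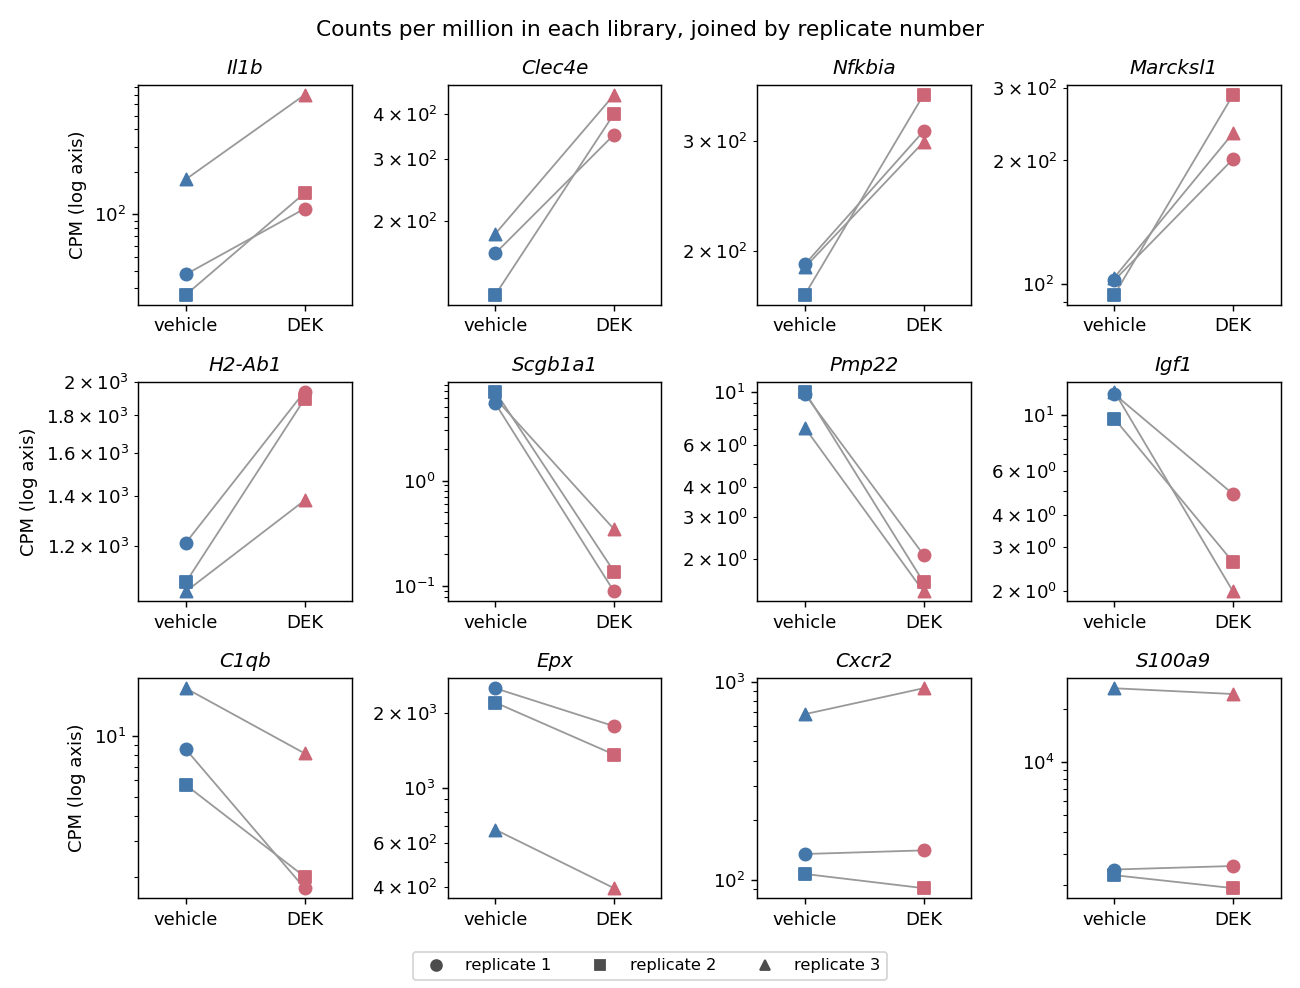
CPM (vertical, log axis with its own range in each panel) of 12 genes in the vehicle and DEK libraries. Each point is 1 library, marker shape gives the replicate number and gray lines join equal numbers. Il1b lay higher in DEK in each pair, Scgb1a1 lay lower, and S100a9 and Cxcr2 lay highest in the libraries numbered 3 of both groups.

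Among the NF-kB response genes, 16 of the 31 tested rose within pairs, 0 fell and 15 did not pass. Adjusted over the list alone, 22 rose and 1 fell. The median log2 fold change was 0.74, and 28 of 31 members were above 0. Called genes were more frequent in the list than among other genes (adjusted p = 6.32e-24, Fisher's exact test, one-sided, which takes genes as independent). Fry gave adjusted p = 0.256 for the list within pairs. Beside Il1b, the members with the smallest p were Cd40, a costimulatory receptor, at 2.20-fold, and the genes of the NF-kB inhibitors Nfkbia and Nfkbie, each at 1.76-fold (adjusted p = 0.00274, 0.00356 and 0.00368, edgeR). Nfkbia is uncertain in that its exons overlap Mir1198 on the opposite strand. Il6 was not past the threshold (log2 fold change -0.31, adjusted p = 0.546, edgeR) and was chosen after its value was seen. In the unpaired fit 0 members passed over all genes, 15 rose adjusted over the list alone, the median was 0.75, and camera gave adjusted p = 1.07e-23, or adjusted p = 0.196 with an estimated correlation.

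Immediate early genes, which respond to stimuli within minutes, had 3 of 33 members rise within pairs, with 11 higher and 2 lower adjusted over the list alone. The members were the phosphatase gene Dusp1 at 1.73-fold, the nuclear receptor gene Nr4a1 at 1.86-fold and Ppp1r15a at 1.72-fold. Ppp1r15a is uncertain, since it overlaps exons of Tulp2 on the opposite strand. The list rose by camera (adjusted p = 3.94e-06; adjusted p = 0.79 with an estimated correlation), with a median of 0.30 and pair medians of 0.06, 0.24 and 0.55. Immediate early genes were also higher in the libraries numbered 3, by a median log2 difference of 0.41 with vehicle and 0.89 with DEK. Class II antigen presentation genes had 2 of 10 members rise, 8 adjusted over the list alone, and all 10 lay above 0 with a median of 0.43 (camera adjusted p = 6.38e-07; adjusted p = 0.79 with an estimated correlation). H2-Ab1 (chromosome 17, 34263227 to 34269418, plus strand) went from 1107 ± 91.0 CPM with vehicle to 1738 ± 310 CPM with DEK (SD, n = 3 each; adjusted p = 0.0159, edgeR).

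Interferon-stimulated genes had 0 of 34 members past the threshold within pairs, over all genes and adjusted over the list alone, although all 34 lay above 0. Their median log2 fold change was 0.63, and the medians of single pairs were -0.15, 0.45 and 1.59 for pairs 1, 2 and 3. Camera called the list higher (adjusted p = 5.99e-08; adjusted p = 0.79 with an estimated correlation). These genes also stood higher in the libraries numbered 3 of both groups, by a median log2 difference of 0.98 with vehicle and 2.40 with DEK. Ifih1 and Mx1, the members with the smallest p, had log2 fold changes of 0.53 and 0.65 (adjusted p = 0.175 and 0.186, edgeR).

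Eosinophil markers were lower in the DEK libraries, with 2 of 10 falling over all genes and 9 adjusted over the list alone. All 10 lay below 0, with a median of -0.49 (camera adjusted p = 3.44e-07; adjusted p = 0.79 with an estimated correlation). Epx, the gene of eosinophil peroxidase, went from 2505 to 1764 CPM in pair 1, from 2195 to 1357 CPM in pair 2 and from 677.7 to 394.3 CPM in pair 3 (adjusted p = 0.0107, edgeR), and Prg3 fell 1.47-fold (adjusted p = 0.0382, edgeR). The eosinophil median was itself lower in the libraries numbered 3, by 1.00 with vehicle and 0.78 with DEK on the log2 scale. Mast cell and basophil markers had 0 of 10 past the threshold, 4 lower adjusted over the list alone and a median of -0.29 (camera adjusted p = 0.00579; adjusted p = 0.79 with an estimated correlation), and Mcpt8 had a log2 fold change of -0.53 (adjusted p = 0.0901, edgeR). The pair medians of this list were -0.24, -0.61 and -0.06, and it was lower in the libraries numbered 3 by 1.17 with vehicle and 0.66 with DEK. Megakaryocyte and platelet markers had 0 of 14 past the threshold, 2 lower adjusted over the list alone and a median of -0.13 (camera adjusted p = 0.0389; adjusted p = 0.79 with an estimated correlation).

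Monocyte and macrophage markers went both ways. Of 17, 2 rose and 3 fell within pairs, with 4 in each direction adjusted over the list alone, and camera did not call the list (adjusted p = 0.442). Cx3cr1, the fractalkine receptor of monocytes, rose 1.54-fold (adjusted p = 0.00827, edgeR), as did Ly6c2 at 1.42-fold (adjusted p = 0.0376, edgeR), a monocyte gene chosen after its value was seen. The complement genes C1qb and C1qc fell 2.99-fold and 2.22-fold (adjusted p = 0.0107 and 0.0339, edgeR). Falling genes were more frequent in the list than among other genes (adjusted p = 0.00135, Fisher's exact test, one-sided, which takes genes as independent).

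Several other fixed lists were called higher by camera within pairs, each with small medians. The targets of cytokine signalling through JAK and STAT proteins had 1 of 20 members rise and a median of 0.22 (adjusted p = 0.00217; adjusted p = 0.79 with an estimated correlation). That member was Cebpd, a transcription factor gene, at 1.55-fold (adjusted p = 0.0107, edgeR), which is uncertain because its exons overlap those of Spidr on the opposite strand. MAPK feedback genes had 0 of 14 past the threshold and a median of 0.21 (adjusted p = 0.0163; adjusted p = 0.79 with an estimated correlation), and myeloid differentiation regulators had 1 rise, that of Cebpd, and 1 fall among 20, with a median of 0.15 (adjusted p = 0.0378; adjusted p = 0.79 with an estimated correlation). Heat shock genes had 0 of 14 and a median of 0.17 (adjusted p = 0.0104; adjusted p = 0.79 with an estimated correlation), led by Bag3 at a log2 fold change of 0.35. Cholesterol synthesis genes had 0 of 20 past the threshold, with 19 of 20 above 0 and a median of 0.18 (adjusted p = 9.1e-05; adjusted p = 0.79 with an estimated correlation). Of the p53 targets and apoptosis genes, 1 of 27 rose, the death receptor gene Fas at 1.92-fold (adjusted p = 0.00124, edgeR), and the list had a median of 0.13 (adjusted p = 0.0136; adjusted p = 0.79 with an estimated correlation). Its pair medians were -0.0032, 0.04 and 0.50, it was not called without pair 3 (median -0.01, adjusted p = 0.547), and it was higher in the libraries numbered 3 by a median of 0.43 with vehicle and 0.74 with DEK. The pair medians of the JAK and STAT targets were -0.01, 0.35 and 0.46 and those of the MAPK feedback genes -0.03, 0.23 and 0.40. G2/M genes had 0 of 30 past the threshold, a median of 0.12 and pair medians of 0.39, 0.27 and -0.31 (camera adjusted p = 0.0298; adjusted p = 0.801 with an estimated correlation). Adjusted over each list alone, 4 JAK and STAT targets, 8 myeloid regulators and 4 p53 targets rose, 1 JAK and STAT target and 1 myeloid regulator fell, and 0 members of the other 4 lists passed.

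Camera called none of the remaining fixed lists within pairs, though some held single called genes. Chemokine genes Cxcl16 and Ccl22 rose 2.06-fold and 1.69-fold (adjusted p = 0.00293 and 0.0266, edgeR), with Cxcl16 uncertain because of its overlap with Zmynd15, and the list of 19 had camera adjusted p = 0.496. Cxcr2, a chemokine receptor gene that was chosen after its value was seen, had a log2 fold change of 0.09 ± 0.12 (SE; adjusted p = 0.839, edgeR) and the receptor list had adjusted p = 0.759, tested toward lower values although its median was 0.01. Sdc4, the gene of a heparan sulfate proteoglycan of the cell surface, rose 1.86-fold, with 0.567 for its list by camera. The glucose transporter gene Slc2a1 rose 1.61-fold and Chac1, a glutathione-degrading enzyme of the stress response, fell 1.90-fold, with 0.288 for glycolysis and hypoxia genes and 0.524 for ER stress and ATF4 genes. Of the neutrophil markers, Lcn2 rose 1.58-fold within pairs (adjusted p = 0.0206, edgeR), and the list had adjusted p = 0.166. Adjusted over the list alone, 3 chemokines were higher and 4 lower, 2 chemokine receptors were higher and 2 lower, 1 gene each was higher among the proteoglycan, glycolysis and neutrophil lists, and 2 ER stress genes were lower.

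No member of the stem and progenitor regulators, stem cell markers, G1/S genes or ribosomal protein genes passed over all genes within pairs, and their camera adjusted p were 0.0945, 0.0773, 0.0798 and 0.0555. Hlf, a transcription factor of stem cells, had a log2 fold change of -0.58 ± 0.13 (SE), was lower in 3 of 3 pairs and lay at the threshold without passing it (adjusted p = 0.05, edgeR). Heterochromatin and histone chaperone genes, a group that DEK itself is known to act with, had 0 of 20 past the threshold and adjusted p = 0.757, with Daxx at a log2 fold change of 0.39 (adjusted p = 0.142, edgeR). Markers of dendritic cells, erythroid cells, B cells, T and NK cells, and endothelial and stromal cells had 0 called members and camera adjusted p of 0.0965, 0.496, 0.597, 0.757 and 0.644. Adjusted over the list alone, 1 stem and progenitor regulator and 1 stem cell marker were lower, and 0 members of the other lists of this paragraph passed.

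**Figure D3:**
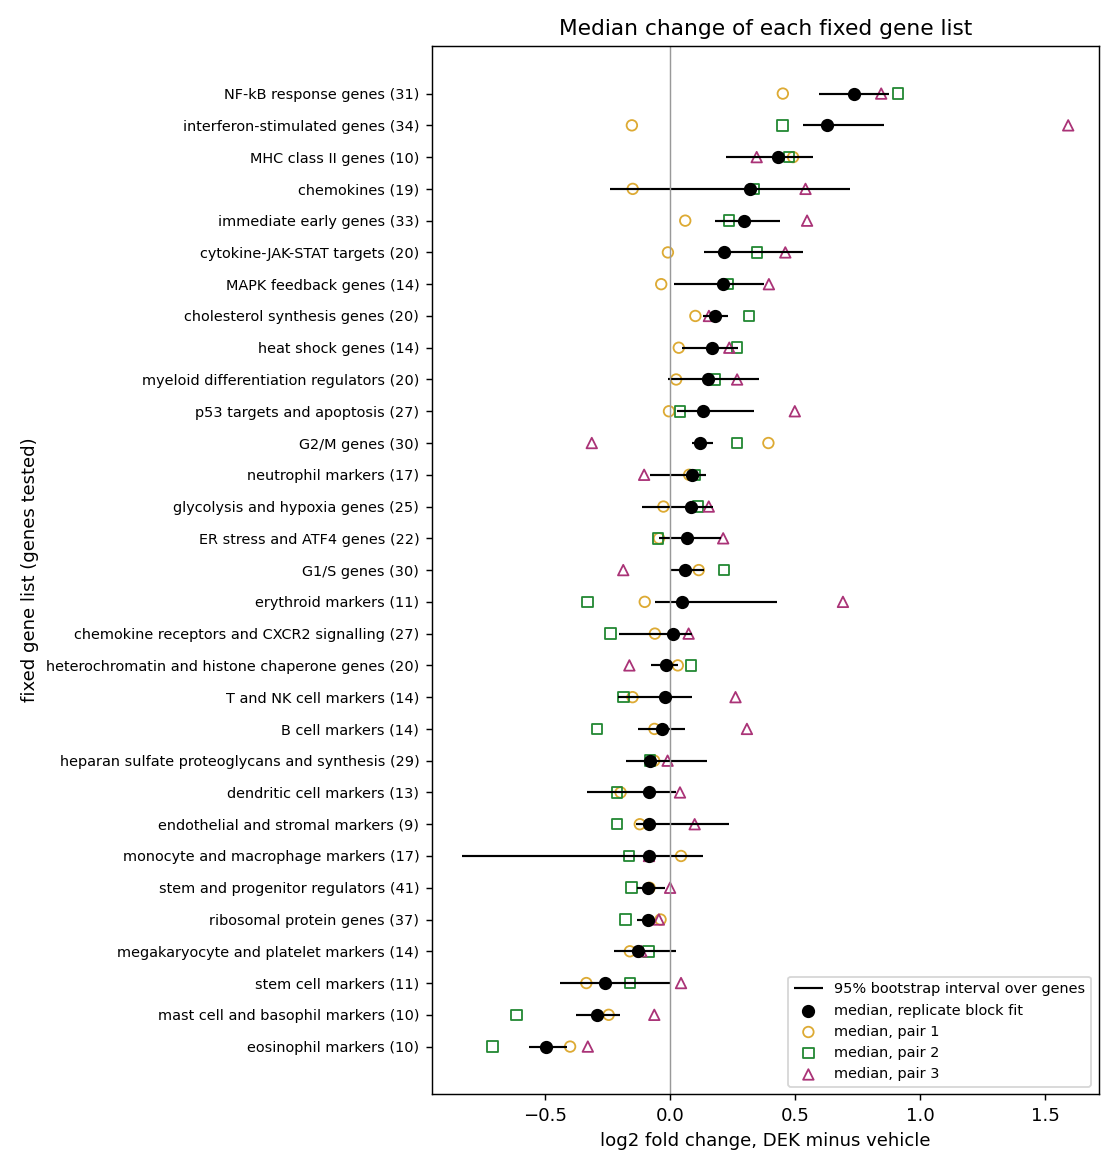
Median log2 fold change, DEK minus vehicle (horizontal), of each fixed gene list (vertical, genes tested in parentheses). Filled points are medians of the fit within pairs, bars their 95% bootstrap intervals over genes, and open markers the medians of single pairs. The NF-kB list lay highest at 0.74 and the eosinophil list lowest at -0.49, and the interferon-stimulated genes spread from -0.15 to 1.59 across pairs.

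Without pairing, camera called 11 lists, 9 higher and 2 lower, against 14 within pairs, 11 higher and 3 lower. None of either set kept its call with an estimated correlation or by fry, a test of whether the members of 1 list move, on balance, one way. Fry's mixed test, for changes in either direction, passed the NF-kB response genes without pairing (adjusted p = 0.0305), and the monocyte and macrophage markers and the megakaryocyte and platelet markers within pairs (adjusted p = 0.0474 each).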

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

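The alternatives to the fit within pairs, the batch block, the exclusion of both libraries numbered 3 and of Rn45s were chosen after seeing the data, and the others were planned. Without a block, the count of 0 changed genes became 51 with DESeq2 (32 higher, 19 lower), 177 with the replicate block, 148 with a block that sets replicate 3 against replicates 1 and 2, and 168 without both libraries numbered 3. Leaving out single libraries gave 0 to 1 genes. Of the 177, 138 were also called with the batch block and 102 without both libraries numbered 3. The count of 177 within pairs became 0 without the block, 344 with DESeq2, 349 with no filter on low counts, 41 at an adjusted p under 0.01 and 47 with a fold change of at least 2. It was 181, 0 and 641 without replicate 1, 2 and 3 of both groups. Against all 3 pairs, the folds of the 47 called genes that the naming rule took were 0.762 to 1.31 times as large without pair 1, 0.57 to 1.15 without pair 2 and 0.681 to 2.71 without pair 3, and moved by over 1.5 times for Klk1b11 without pair 2 and for Klk1b11, Scgb1a1 and Tnfaip8l3 without pair 3. The other alternatives within pairs gave 150 to 231 genes. None of the 47 kept its call without pair 2, 30 did without pair 1 and 44 without pair 3. None changed sign, but this could hardly be otherwise, since each of the 177 called genes moved the same way in all 3 pairs. All 47 kept their calls with DESeq2 and both other scalings. Calls were lost by 6 with limma-voom (Tnfaip8l3, Cd300e, Zmynd15, Fabp3, C1qc, Prg3), by 5 with thinned counts (among them Cp, Mcam, Gas6 and Aldh1l2), by Cp and Mcam with the stricter filter, by Cp and Smpdl3b with no filter and by Prg3 without Rn45s. The causes were not tested. Without a block camera called 11 lists, against 0 with an estimated correlation, 0 by fry and 18 without both libraries numbered 3, which held 10 of the 11. Leaving out single libraries gave 5 lists (without DEK replicate 3, 4 of them among the 11) to 19 (without vehicle replicate 3, 9 of them among the 11). Within pairs camera called 14, against 0 with an estimated correlation and 0 by fry. Without replicate 1, 2 or 3 of both groups it called 13, 9 and 18 lists, which held 12, 9 and 10 of the 14. The calls lost were those of the G2/M and megakaryocyte lists without replicate 1, of the MAPK, myeloid regulator, G2/M, heat shock and mast cell lists without replicate 2, and of the MAPK, myeloid regulator, p53 and megakaryocyte lists without replicate 3.

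Every named gene whose log2 fold change changed sign was uncalled in the fit concerned, but the fit without a block called 0 genes in all. Mcam, Dusp1, Ppp1r15a and Lcn2 changed sign in that fit and were called higher within pairs. Without a block, leaving out single libraries gave -0.46 to 2.81 for Mcam, -0.023 to 1.56 for Dusp1, -0.46 to 2.06 for Ppp1r15a, -0.44 to 1.22 for Phlda1, -0.0446 to 0.52 for E2f2, -1.201 to 2.44 for Lcn2 and -0.41 to 1.72 for Slc4a1, each lowest without DEK replicate 3 and highest without vehicle replicate 3. The ranges were -0.85 to 0.20 for Cd3d and -3.37 to 1.28 for Col1a1, with the same libraries at the same ends. Dek was 0.0109 without both libraries numbered 3. Within pairs, leaving out pairs gave -0.19 to 0.0112 for Dek, highest without replicate 3, and -0.24 to 0.000966 for Pecam1, highest without replicate 2.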

Other observations

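The tests of the NF-kB, macrophage and replicate 3 patterns below, other than that of a microbial product, were chosen after the result was seen, and so were the genes named in this part. Beyond the genes the naming rule took, several others known from innate inflammation rose within pairs. Tlr2, a receptor for bacterial lipoproteins, had a log2 fold change of 0.98 ± 0.13 (SE), the inflammasome gene Nlrp3 0.83 ± 0.11 and Icam1, an adhesion molecule, 1.08 ± 0.14 (adjusted p = 0.00991, 0.00599 and 0.0107, edgeR). The mitochondrial superoxide dismutase gene Sod2 rose by 1.199 ± 0.155 and Relb, a subunit of NF-kB, by 1.03 ± 0.15 (adjusted p = 0.0157 and 0.0184). Saa3, an acute-phase gene, stood at 91.5 ± 25.5 CPM with vehicle and 532 ± 232 CPM with DEK (SD, n = 3 each) and was higher in 3 of 3 pairs, but did not pass (adjusted p = 0.394). Tnf, at 18.2 ± 8.56 and 50.3 ± 22.9 CPM (SD, n = 3 each), did not pass either (adjusted p = 0.148).

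Trem2, Fabp4 and Pparg, known from lipid-handling macrophages, fell within pairs. Trem2, a lipid receptor, had a log2 fold change of -1.25 ± 0.17 (SE), the fatty acid binding protein gene Fabp4 -1.13 ± 0.17 and the nuclear receptor gene Pparg -0.84 ± 0.15 (adjusted p = 0.013, 0.013 and 0.0195, edgeR within pairs). Apoe and Gpnmb were far more abundant, with Gpnmb at 1230 ± 257 CPM with vehicle and 421 ± 116 CPM with DEK (SD, n = 3 each), yet neither passed (adjusted p = 0.46 and 0.268). Their log2 differences were -2.06, -2.62 and -0.77 for Apoe and -1.98, -1.94 and -0.75 for Gpnmb in pairs 1, 2 and 3. A test of whether the DEK effect in pair 3 differed from that in pairs 1 and 2 called 0 of the genes by edgeR (smallest adjusted p = 0.0534), with 1030 at an unadjusted p under 0.05. Interferon-stimulated Gbp4, Herc6 and Ifit3, with Axl, Apoe and Gpnmb, were among the smallest p. Pair 3 holds 1 vehicle and 1 DEK library, so the spread in this test came from pairs 1 and 2 alone.

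Of 167 genes called from pairs 1 and 2 alone without a block, 148 (88.6%) had the same direction in pair 3, 84 of 92 that were higher and 64 of 75 that were lower. Across all genes tested, 49.5% were higher and 50.5% lower in pair 3. Across genes, which are not independent replicates, the log2 differences of pair 3 correlated by 0.07 with those of pair 1 and by 0.28 with those of pair 2, and pairs 1 and 2 correlated by 0.28.

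For the number of genes called, the splits of the libraries are too few to give a share under 0.05. Without a block, the real split gave 0 genes and the highest other split 0, so 10 of 10 splits gave as many. Within pairs, 4 splits part all 3 pairs. The real one gave 177 genes and the highest other 0, so 1 split gave as many, while splits that keep a pair together gave 0 to 9.

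The higher NF-kB response genes could reflect more neutrophils in the DEK libraries. The upper 95% bound of the neutrophil marker median, 0.143 on the log2 scale, lay below the lower bound of 0.597 for the NF-kB list. These bounds cover genes and not the spread between libraries, and neutrophil markers need not move together. In DEK replicate 3, only 12 of 17 were above DEK replicates 1 and 2, with an interval of the median from -0.20 to 3.46. The low median thus speaks only for the list as a whole, and more neutrophils of some kinds stay open. More monocytes stay open as well. The 7 monocyte markers had a median of 0.07 and an upper bound of 0.504, also below 0.597. They went both ways, from Ly86 at -0.17 ± 0.11 (SE) to the called Ly6c2 at 0.50 ± 0.11 and Cx3cr1 at 0.63 ± 0.09. A microbial product in the protein preparation may raise the same genes, and the prediction for it was a lower bound of the interferon-stimulated median above 0. That bound was 0.532, but it covers genes only, and no value could have excluded such a product. Of the 34 members 0 passed, and the pair medians were -0.15, 0.45 and 1.59. No library had the preparation without DEK, so a microbial product cannot be told apart from an effect of DEK. A change of state within any cell type also stays open.

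For the lower macrophage genes, a candidate explanation is an even loss of all macrophages from the DEK libraries. The log2 fold changes of C1qa, C1qb, C1qc, Mrc1, Cd163 and Vcam1 shared no common value within joint 95% intervals, since the interval of Cd163 lay 0.539 above that of C1qb. C1qb stood at -1.58 ± 0.22 and Cd163 at 0.13 ± 0.14 (SE). The interval of Vcam1, -0.67 to 0.30, also lay above that of C1qb, whose upper bound was -0.84. That of Mrc1, -8.29 to 5.24, was too wide to tell. Marco was left out after its value was seen, because it lay under 1 CPM with vehicle. An even loss is thus argued against only if these transcripts come from macrophages alone, which was not tested. Vcam1 stood at 303.9 CPM with vehicle, against 10.5 CPM for C1qb and 10.7 CPM for Cd163. Loss of a subset of macrophages low in Cd163 and Vcam1, a change of their state and another source of these transcripts stay open. With another source, an even loss would stay open too.

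The libraries numbered 3 may come from a less complete depletion of every lineage. Against that, B cell markers were lower in them in both groups, with the upper 95% bound of the median log2 difference at most -0.499. A failure for neutrophils and erythroid cells alone stays open, since erythroid medians were higher by 1.196 with vehicle and 2.16 with DEK. Dilution of all other cells by neutrophils alone would lower every other type alike. The intervals of the stem cell and the B cell markers were at least 0.138 apart in both groups. These lists were picked as the most separated of those compared, and the intervals cover genes and not the spread between libraries. The gap alone therefore does not decide, though the higher erythroid medians are also not what such dilution would give. A difference of animals or of the day of preparation was not tested, since the labels give neither.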
